A study of Mus musculus with 5 samples.

How the data were processed

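Total RNA from fresh heart tissue in 5 samples of male mice of the C57BL/6 background was labelled with biotin by a whole-transcript kit, per the labels' protocols. The deposited values are log2 signals, 1 per probe set and array, rounded to 2 decimals. Per the submitters' processing notes they were made with Affymetrix Expression Console; its version and the summarisation algorithm are not given in the sources used here. The values ran from 1.27 to 13.66, the arrays had close but not identical quantiles, and the base of the logarithm was read from that range. If the arrays were normalized to each other, as their close quantiles would fit, a change shared by most genes would not show; how this was done was not tested. Background, if not fully removed, would make fold changes of dim genes too small.

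The table held 41345 probe sets. The platform annotation gave 23521 of them exactly 1 gene symbol and 1814 several, and did not list 16010, which were unnamed here and tested only apart. Symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, where 23328 matched and 0 symbols changed; no build is named for the array values, so no coordinates are given. The 23521 probe sets covered 22180 genes, 1082 of them with more than 1 probe set. Each gene was represented by the probe set with the highest mean over all 5 arrays. Of 991 tested genes with several probe sets, 6 had probe sets whose group differences were over 1 log2 unit apart. Genes under the 30th percentile of mean signal (log2 4.06) were left out, which left 15528.

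The groups were read from the sample titles, 3 wild type and 2 Akita arrays. Akita minus wild type was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. The fit had 3 residual and 4.38 prior degrees of freedom, and the median SD within groups was 0.144 on the log2 scale. A count at an unadjusted p under 0.05 with a fold of at least 1.5 was added as a description. Camera with a preset correlation of 0.01 tested the gene lists with at least 4 measured genes, adjusted over the lists; camera with an estimated correlation and fry were alternatives. The 45 lists held 875 genes, of which 795 were on the array. Several list genes were not analysed here. Pearson correlations between arrays, across genes, were 0.984 to 0.992 within groups and 0.978 to 0.985 between them, where genes are not independent replicates. The lowest value within a group, 0.984, was that of the 2 Akita arrays and lay under the highest between groups. Scores on the first principal component were 28.5 and 6.69 in Akita replicates 1 and 3 and -16.4, -15.9 and -2.94 in the wild type arrays. This component held 47.6% of the variance. The groups accounted for 41.9%, where 25% is given by chance, and an exact permutation test of 3 against 2 arrays cannot go below 0.1 one-sided.

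The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Named genes were the 12 highest and 12 lowest log2 differences among genes past the threshold whose groups did not overlap, filled up where fewer passed with the smallest unadjusted p among non-overlapping genes differing by at least 0.5, leaving out predicted, small RNA and receptor symbols; the up to 4 members with the smallest p of each list; and a set of genes known from diabetic hearts. Pck1, Sln, Myl7, Bpgm, Slc4a1, Gcg and the genes named in the closing part outside these lists were chosen after their values were seen. The alternatives were no filter on dim genes or a filter at the 50th percentile, the mean of all probe sets, quantile normalization again, centring of arrays, an intensity trend with a robust prior, array weights, each array left out, a threshold of 0.1, an unmoderated model and a fold of 2. With an array left out of the Akita group, the remaining array was assumed to vary like the others. The labels name no batch, so none was modelled. On simulated data with 200 of 15528 genes changed, the test recovered 79% of log2 changes of 1 and 99% of log2 changes of 2, with 7 false among 185 calls and 0 calls when no gene was changed. Without changes, 2.5% of random lists had a camera p under 0.05. Genes were simulated as independent, so this does not show how camera with the preset correlation behaves on lists of correlated genes. In the 10 lists called in the real data, the estimated correlation ran from 0.0914 to 0.767. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.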

Results

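Transcript levels were measured on 5 whole-transcript arrays of heart RNA from male C57BL/6 mice aged 12 weeks. The wild type group held 3 arrays (replicates 3, 4 and 5) and the Akita group 2 arrays (replicates 1 and 3). Akita mice carry a mutation in a single copy of Ins2, an insulin gene, and become diabetic because the misfolded protein harms the insulin-producing cells. The median log2 signal per array was 4.53, 4.56 and 4.62 in the wild type hearts and 4.71 and 4.6 in Akita replicates 1 and 3. The number of arrays limits the precision of every value. The labels number the samples without saying whether each came from a separate animal, so the p-values measure the spread between these samples, which can be partly technical. The Y-linked genes Kdm5d, Uty and Eif2s3y lay at 6.47, 7.30 and 8.31 on the log2 scale in the wild type mean and at 6.19, 7.12 and 8.49 in the Akita mean. Ins2 itself lay at 3.70 ± 0.23 (SD, n = 3) in wild type and 3.66 ± 0.04 (SD, n = 2) in Akita hearts, under the filter on dim genes, and since the mutation leaves the transcript in place its probe set checks no label.

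The comparison of Akita with wild type asked how the diabetic heart differs in its transcripts. Ccn2, a secreted matrix-associated growth regulator, rose in the Akita hearts from 7.80 ± 0.08 (SD, n = 3) to 8.78 ± 0.12 (SD, n = 2; log2 difference 0.98, SE 0.12, adjusted p = 0.0285). Ier3, a stress-inducible survival gene, fell from 8.99 ± 0.14 to 7.71 ± 0.25 (log2 difference -1.28, SE 0.15, adjusted p = 0.0265). Genes of fatty acid use lay higher as a group (camera adjusted p = 8.17e-05, but 0.812 with an estimated correlation), with the smallest p in Pdk4, the kinase that restrains pyruvate dehydrogenase, at 11.03 ± 0.21 in wild type and 12.21 ± 0.28 in Akita hearts (log2 difference 1.18, SE 0.17, adjusted p = 0.0550). The highest rise among the named genes was in Srsy, a multi-copy locus, from 4.51 ± 0.15 to 8.68 ± 0.14 (log2 difference 4.17, SE 0.13, adjusted p = 4.25e-05). In all, 51 of 15528 genes passed an adjusted p of 0.05 by limma, 33 higher and 18 lower in Akita, and in each of them both Akita arrays lay outside the range of the wild type arrays. Centring each array on its median adds the same amount to each gene's group difference, so medians of gene sets move up by construction. The median difference over the genes tested thereby went from -0.0317 to 0.0625, and the split of calls became 25 higher and 5 lower. The calls numbered 9, 17 and 26 without wild type replicate 3, 4 or 5 and 11 without Akita replicate 3, and 40 without Akita replicate 1, of which 14 were among the 51. Of the genes tested, 2116 had an unadjusted p under 0.05, where chance gives 776, and 342 of these differed by at least 1.5-fold, 147 higher and 195 lower, or 242 higher and 85 lower with the arrays centred. In 4618 genes (29.7%) the groups did not overlap, where chance gives 20%.

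Of the 33 genes that rose, 24 were predicted models, small RNA loci or chemoreceptor genes: 12 Gm or Rik models, 4 microRNA loci, 2 small nucleolar RNA loci, 5 olfactory or vomeronasal receptor genes and a 5S rRNA. The other 9 included Srsx (log2 difference 2.83) and Astx5 (3.06), both multi-copy loci on the X chromosome, BC061237 (2.05) and the histone gene H2bc3 (1.62). Scgb2b7 rose by 1.28, Speer4cos by 1.04 and Cyp1a1, a xenobiotic-metabolising oxidase, by 0.99, with adjusted p = 0.0355, 0.0299 and 0.0424. In 27 of the 33 the wild type mean was under 6. Astx5 has 5 probe sets and Srsy 7, and 5 of the genes that rose have probe sets of identical values, so those signals cannot be assigned to single loci. Ccn2 has a second probe set, dimmer, that differed by 0.035. Cd207 (0.78, adjusted p = 0.0532) and Btbd35f1 (1.11, adjusted p = 0.0600) missed the threshold.

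The genes that fell were brighter, with a wild type mean of 7 or more in 15 of 18. Besides Ier3 they included Pfn1, which encodes the actin-binding protein profilin, from 10.26 ± 0.10 to 9.31 ± 0.06 (log2 difference -0.95, SE 0.11, adjusted p = 0.0285), and the small GTPase gene Rras (log2 difference -0.96, adjusted p = 0.0265). Sh3bgrl3 (-1.21), Nudt22 (-1.03) and Vsig2 (-0.99) fell too, as did Bod1, from 9.86 ± 0.08 to 8.86 ± 0.09. Cited4, a transcriptional co-regulator, fell from 7.85 ± 0.13 to 6.84 ± 0.13, and Higd2a, a gene of respiratory complex assembly, from 10.88 ± 0.12 to 9.91 ± 0.05. Trmt112 (-0.93), the long non-coding RNA Neat1 (-0.91) and Cuta (-0.90) completed the named set. Bod1 has a second, dimmer probe set that differed by 0.14. The number of genes that fell was 0 without wild type replicate 3 or 4, 3 without wild type replicate 5 or Akita replicate 1, and 1 without Akita replicate 3. The 18 genes had a median genomic span of 3.4 kb, against 20.2 kb over all genes tested.

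**Figure D1:**
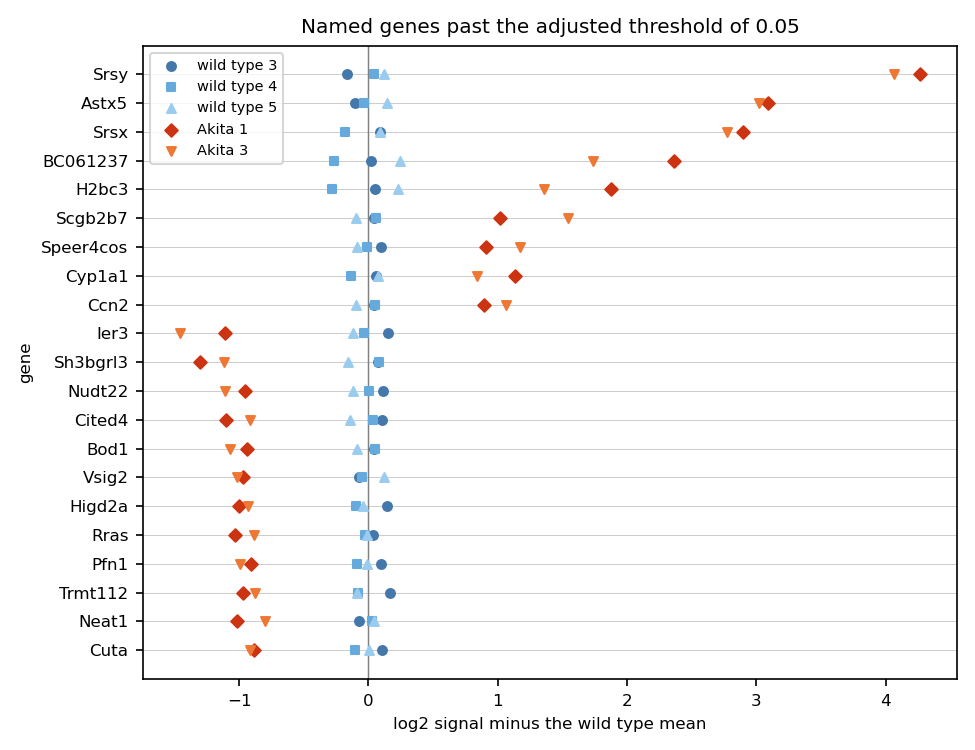
Log2 signal of each array minus the wild type mean (horizontal axis, log2 units) for the 21 named genes past the adjusted threshold (vertical axis); each point is 1 array, blue for wild type and red or orange for Akita. Both Akita points lie outside the wild type points in every gene, from 4.17 on average for Srsy to -1.28 for Ier3.

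Fatty acid uptake and oxidation, the targets of PPAR-alpha, formed the only list whose call held with each array left out. Of its 34 genes, 26 lay higher and 8 lower in Akita, 0 passed over all genes, and 4 rose when adjusted over the list alone. These were Pdk4, the mitochondrial uncoupling protein gene Ucp3 (log2 difference 1.26, SE 0.21, adjusted p = 0.0785), Angptl4, an inhibitor of lipoprotein lipase (log2 difference 1.97, SE 0.45, adjusted p = 0.161), and Cpt1a, which admits long-chain fatty acids to mitochondria (log2 difference 0.49, SE 0.11, adjusted p = 0.166). Angptl4 lay at 6.47 in Akita replicate 1 and 8.23 in replicate 3, against 5.38 ± 0.24 in wild type. Cd36, the fatty acid transporter, differed by 0.14 (adjusted p = 0.603). The median over the list was 0.12 and the camera adjusted p was 8.17e-05, while adjusted p = 0.812 with an estimated correlation. The weakest value with an array left out was 0.0108, without Akita replicate 3. White adipocyte markers lay higher in the same arrays and by more, with list medians of 0.32 and 0.47 in Akita replicates 1 and 3 against 0.10 and 0.16 for this list.

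**Figure D2:**
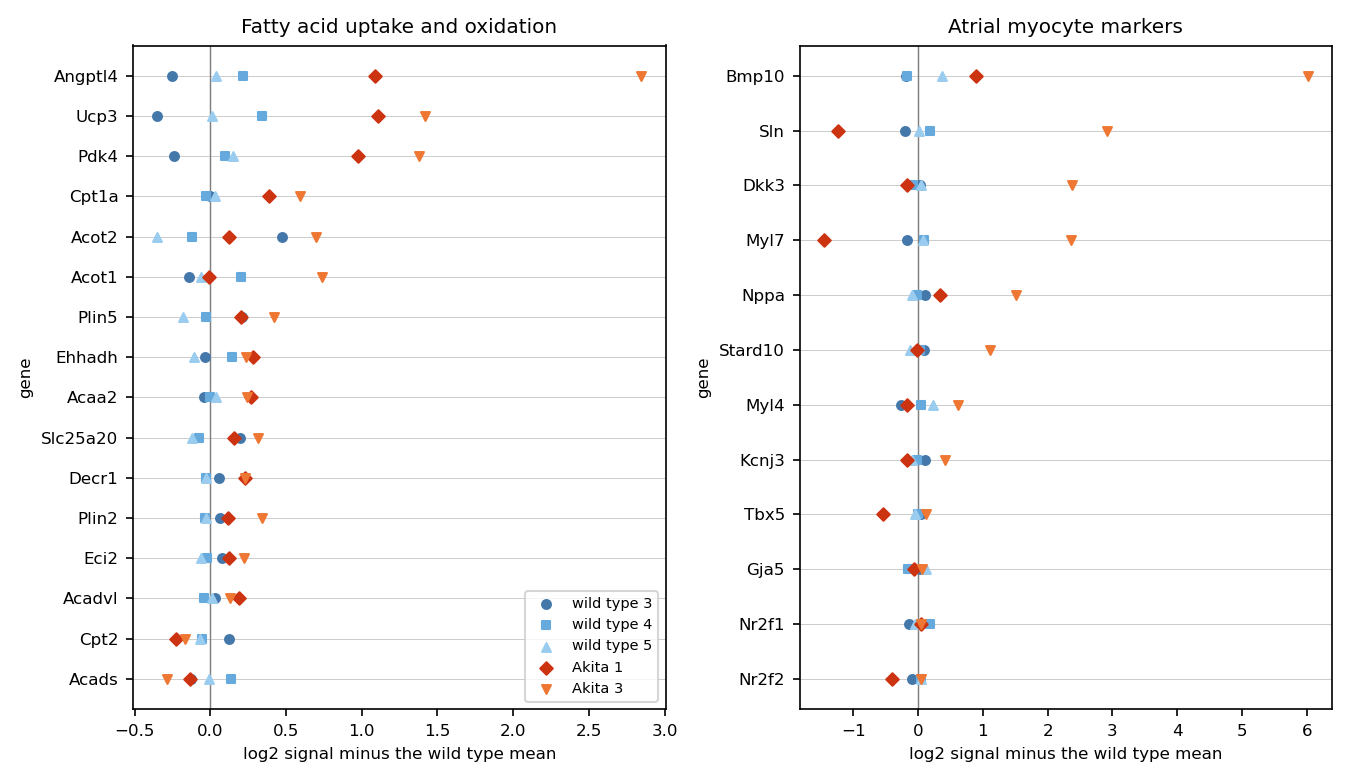
Log2 signal minus the wild type mean (horizontal axes, log2 units) for 16 genes of fatty acid use (left) and 12 atrial myocyte markers (right), 1 point per array. Both Akita arrays lie above wild type for Angptl4, Ucp3, Pdk4 and Cpt1a, whereas Bmp10, Sln and Myl7 stand highest in Akita replicate 3.

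Genes of glucose use lay lower without a call. Bright genes in general lay lower too, with a median of -0.07 over the genes left by a filter at the 50th percentile. Slc2a4, the insulin-responsive glucose transporter, stood at 9.78 ± 0.01 in Akita and 10.17 ± 0.14 in wild type (log2 difference -0.39, SE 0.12, adjusted p = 0.247), and Slc2a1 differed by -0.41 (adjusted p = 0.286). Of 22 genes of glucose uptake and glycolysis, 16 lay lower and 0 passed either adjustment (median -0.09, 0.0025 with the arrays centred; camera adjusted p = 0.0678). In glycogen metabolism (13 genes, camera adjusted p = 0.199), 2 genes fell when adjusted over the list alone and 0 over all genes: Ppp1r3b, a glycogen-targeting phosphatase subunit, and Gys1, muscle glycogen synthase, with log2 differences of -0.61 and -0.49. Insulin and IGF signalling (24 genes, camera adjusted p = 0.604) held Irs2 at -0.46 and Foxo3 at -0.43, neither past an adjusted threshold. FoxO targets and muscle atrophy (20 genes, 0.757) had Txnip, a glucose-responsive inhibitor of thioredoxin, as the gene that rose over the list alone (0.76, adjusted p = 0.135 over all genes). Among glucocorticoid-responsive genes (18 genes, 0.908), Pdk4 and Angptl4 rose over the list alone. Camera adjusted p was 0.0576 for branched-chain amino acid catabolism (17 of 19 genes lower; median -0.10, -0.01 with the arrays centred), 0.615 for ketone body metabolism, 0.869 for the tricarboxylic acid cycle, 0.301 for triglyceride storage and 0.991 for sterol and fatty acid synthesis, each with 0 members past either adjustment.

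Genes of energy conversion and defence against oxidants lay slightly lower in the values as deposited. So did bright genes in general, with a median of -0.07 over the genes left by a filter at the 50th percentile. With that filter the camera adjusted p was 0.228 for the respiratory chain and 0.209 for oxidative stress genes. In the respiratory chain and ATP synthase, 34 of 38 genes lay lower, 0 passed over all genes and 1 fell over the list alone, Cox6a2, a heart and muscle subunit of cytochrome oxidase (log2 difference -0.54, SE 0.11, adjusted p = 0.125). The list median was -0.10, or 0.00 with the arrays centred and -0.05 with quantile normalization again (camera adjusted p = 0.0468), with adjusted p = 0.812 with an estimated correlation; the call ended with either (0.152 and 0.161) and without Akita replicate 3 (0.772), wild type replicate 4 (0.0577) or wild type replicate 5 (0.152). Among oxidative stress genes, 22 of 30 lay lower, and 1 fell over the list alone and 0 over all genes, the glutathione transferase gene Gstp1 (log2 difference -0.86, SE 0.16, adjusted p = 0.116). Its call (median -0.19, -0.09 with the arrays centred and -0.08 with quantile normalization again; adjusted p = 0.0480; adjusted p = 0.812 with an estimated correlation) ended with either (0.0707 and 0.230) and without Akita replicate 1 (0.0804), Akita replicate 3 (0.204) or wild type replicate 3 (0.151, median -0.10).

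Immediate early genes, which respond within minutes to stimulation, lay lower in 18 of 23 cases. Ier3 fell over all genes, and Nr4a3 (log2 difference -0.80, SE 0.19, adjusted p = 0.167) and Klf2 (log2 difference -0.60, SE 0.15, adjusted p = 0.180) fell with it when adjusted over the list alone. Nr4a1 differed by -1.16 (adjusted p = 0.229); without Akita replicate 3 it differed by -0.62 and Klf2 by -0.38. The list's call (median -0.24, -0.15 with the arrays centred; camera adjusted p = 0.00802; adjusted p = 0.812 with an estimated correlation) ended without wild type replicate 5 (0.0832) or Akita replicate 3 (0.248). Interferon response genes lay lower in 16 of 19 cases, among them Oas2 (-0.46 ± 0.12) and Irf9 (-0.35 ± 0.13) (log2 difference ± SE), with 0 past either adjustment. That call (median -0.22, -0.12 with the arrays centred and -0.04 without Akita replicate 1; adjusted p = 0.0480; adjusted p = 0.812 with an estimated correlation) ended when Akita replicate 1 (0.436), Akita replicate 3 (0.0560), wild type replicate 4 (0.233) or wild type replicate 5 (0.0685) was left out. The clock list, with Per3 at -0.47 and Dbp at -0.46, had 13 of 17 genes lower (median -0.20, -0.03 without Akita replicate 1) and a camera adjusted p of 0.0589. For autophagy it was 0.0694, for heat shock proteins 0.481, for the unfolded protein response 0.991, for apoptosis 0.712 and for inflammatory cytokines, receptors and adhesion 0.258. Bag3, a co-chaperone, fell over the heat shock list alone (-0.56, adjusted p = 0.137 over all genes).

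Genes of contraction and calcium handling gave no camera call as lists, while fry for either direction gave adjusted p = 0.0148 for the sarcomere, 0.0113 for calcium handling, 0.0226 for cardiac channels and 0.00658 for the fetal programme. That test called 21 of the 42 lists, glucose uptake and heat shock proteins among them at 0.0113 each, so its calls were not particular to contraction. Myh6 and Myh7, the adult and fetal myosin heavy chains, differed by 0.00 and 0.43 (0.01 for Myh7 without Akita replicate 3), and Atp2a2 and Pln, the sarcoplasmic calcium pump and its inhibitor, by -0.03 and -0.07, all with adjusted p over 0.4. Nppa, the atrial natriuretic peptide gene, lay at 12.21 in Akita replicate 1 and 13.39 in replicate 3, against 11.88 ± 0.10 in wild type (adjusted p = 0.274), and Nppb differed by 0.48 (adjusted p = 0.343; 0.22 without Akita replicate 3). In the fetal gene programme (18 genes, camera adjusted p = 0.199), Ccn2 rose over all genes and skeletal actin, Acta1, fell over the list alone (-0.57, adjusted p = 0.140 over all genes). Calcium handling (0.272), sarcomere (0.6) and microRNA biogenesis (0.258) lists had 0 members past either adjustment, and Dicer1 differed by -0.25 (-0.13 without Akita replicate 1). Among cardiac potassium and sodium channels (0.453), Kcnd2, a transient outward current gene, fell over the list alone (log2 difference -0.64, SE 0.14, adjusted p = 0.139).

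Matrix, atrial and surface-layer genes lay higher in 1 of the 2 Akita hearts. In extracellular matrix and fibrosis, 31 of 36 genes lay higher; Ccn2 rose by either adjustment, while Lum (0.58), Col6a1 (0.47) and Postn (0.55) did not pass and lay at 0.33, 0.30 and 0.23 without Akita replicate 3. The list median was -0.06 in Akita replicate 1 and 0.39 in replicate 3, as log2 signal minus the wild type mean. Markers of atrial myocytes stood at -0.17 and 0.87 in the same arrays and cardiac fibroblast markers at 0.00 and 0.43. Epicardium and mesothelium markers stood at 0.01 and 0.57 and cell division genes at 0.02 and 0.25. The cell division genes of smallest p were dim, with wild type means of 4.42 (Cenpe), 4.38 (Bub1b), 5.05 (Ccnb2) and 5.72 (Mcm6). Dim genes lay slightly higher in general, with a median of 0.0667 over the 11100 dimmer genes. With a filter at the 50th percentile the camera adjusted p for cell division was 0.00284. The matrix list's call (camera adjusted p = 0.00125; adjusted p = 0.812 with an estimated correlation) turned direction without Akita replicate 3, with a median of -0.06 and adjusted p = 0.726. For cell division, 24 of 25 genes lay higher with 0 past either adjustment, Cenpe leading at 0.45, and adjusted p = 8.17e-05 became 0.186 without Akita replicate 3; adjusted p = 0.812 with an estimated correlation. Epicardial markers, 7 of 10 higher with 0 past either adjustment, had adjusted p = 0.0468 (adjusted p = 0.812 with an estimated correlation), which became 0.613 without Akita replicate 3 and ended as well without each wild type array, at 0.0628, 0.0510 and 0.0685 for replicates 3, 4 and 5. Atrial and fibroblast markers were not called, both at adjusted p = 0.0532.

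**Figure D3:**
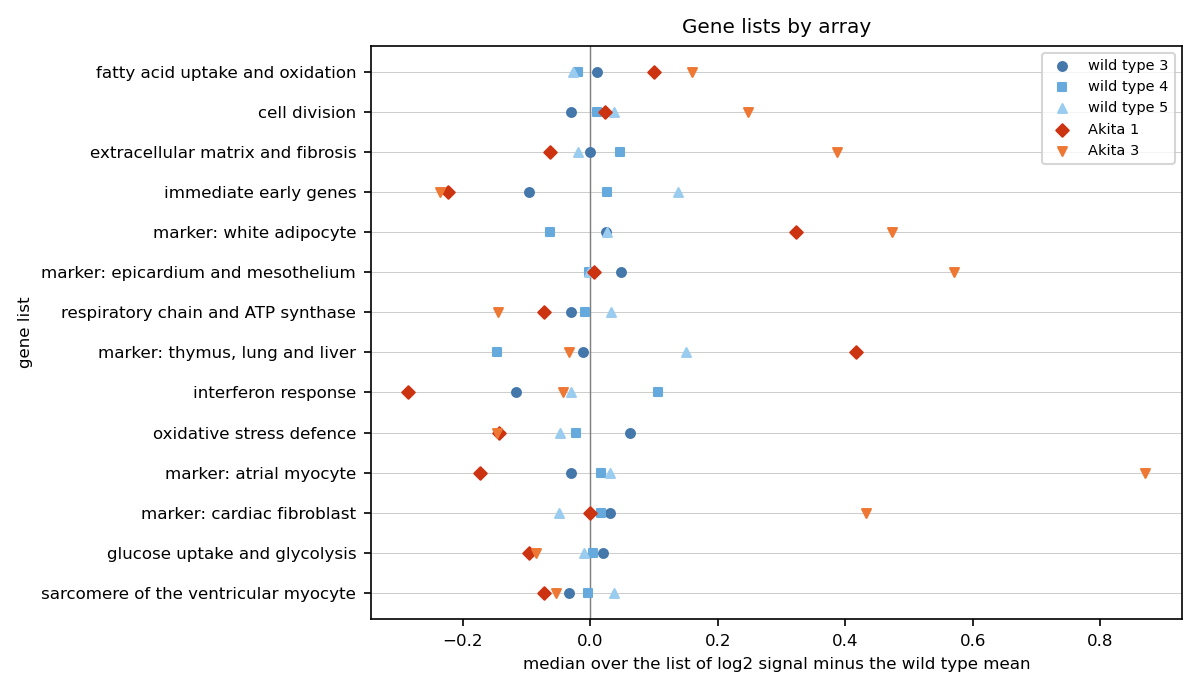
Median over each gene list of log2 signal minus the wild type mean (horizontal axis, log2 units), 1 point per array. Akita replicate 3 stands at 0.87 for atrial markers and 0.57 for epicardium, with Akita replicate 1 at -0.17 and 0.01, whereas both Akita arrays lie above wild type for fatty acid genes.

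Adipocyte markers lay higher in both Akita hearts, with list medians of 0.32 and 0.47. Of 8 white adipocyte markers, 0 passed over all genes, while 5 rose and 1 fell over the list alone. They included Pck1, a gluconeogenic enzyme (1.19, 0.50 without Akita replicate 3), the lipid droplet genes Cidec (0.78, 0.40 without it) and Plin1 (0.46), Retn (0.43) and, in the other direction, Slc36a2 (-0.60). The call (camera adjusted p = 0.00981; adjusted p = 0.812 with an estimated correlation) ended without Akita replicate 3 (0.112). Brown adipocyte markers were not called (0.0532), and Ucp1 rose over that list alone, at 5.35 and 6.82 in the Akita arrays against 4.25 ± 0.10 in wild type (adjusted p = 0.131 over all genes). Thymus, lung and liver markers lay higher in all 6 genes, with list medians of 0.42 in Akita replicate 1 and -0.03 in replicate 3, with 0 members past either adjustment. Their adjusted p of 0.0480 (adjusted p = 0.812 with an estimated correlation) became 0.866 without Akita replicate 1, 0.106 without wild type replicate 3 and 0.111 without wild type replicate 4. Cd68, a lysosomal macrophage gene, fell over the macrophage list alone (log2 difference -0.84, SE 0.14, adjusted p = 0.0773), though the list was not called (0.305), and Ly6c1 fell over the endothelial list alone (log2 difference -1.21, SE 0.17, adjusted p = 0.0532; list 0.869). Skeletal muscle markers were at 0.869, with Acta1 the gene that fell over the list alone. Markers of T and NK cells (0.401), B cells (0.869), granulocytes (0.604), Schwann cells and neurons (0.272) and smooth muscle and pericytes (0.997) were not called and had 0 members past either adjustment. Tnf and Mmp9 differed by 0.06 and 0.01.

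Across the 42 lists tested, camera with its preset correlation called 10, 6 higher and 4 lower, and 17 had an unadjusted p under 0.05. With the arrays centred, the medians of the 6 lists called higher lay between 0.21 and 0.47, a rise that centring gives to every list. With an estimated correlation 0 were called and 0 had an unadjusted p under 0.05. Fry called 0 lists in a direction, with 5 at an unadjusted p under 0.05, and 21 for change in either direction. Median and test differed in sign for apoptosis, FoxO targets, endothelial markers, glucocorticoid-responsive genes and the unfolded protein response, and median and mean differed in sign for B cell markers, none of them called. Erythroid markers, sex markers and pancreatic hormone genes had fewer than 4 genes above the filter and were not tested: Slc4a1 and Bpgm, of red cells, differed by 0.23 (0.09 without Akita replicate 1) and -0.23 (-0.09 without wild type replicate 3), and Gcg, the glucagon gene, by -0.02.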

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

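The test of dim signals and the use of unlisted probe sets were chosen after the data were seen. The tests of receptor genes, of probe sets of several genes and of germ-cell RNA address a rise already seen in the called genes. Only their criteria were fixed before their own results. Signal outside the gene comparison came from probe sets the annotation ties to several genes and from probe sets it does not list. Of 1270 tested probe sets of several genes, 227 were higher and 51 lower in Akita at an adjusted p of 0.05. Of 11210 tested unlisted probe sets, 207 were higher and 40 lower. Groups of the 207 shared their log2 difference and adjusted p by limma, such as 1.408 and 0.0289, and so can repeat the same signal. These counts are therefore of probe sets and not of separate signals. No gene was named from either kind.

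Among the 33 genes that rose were loci with no known role in the adult heart, such as Srsy, Astx5 and 5 olfactory or vomeronasal receptor genes, and 5 of the 33 have probe sets of identical values. Germ-cell RNA was argued against, since 23 spermatogenic markers had a median log2 difference of 0.1 (bootstrap SE 0.061, highest 0.367), and so was a shift of all dim signals, since the 11100 dimmer genes of the 22180 had a median of 0.0667 (bootstrap interval 0.0633 to 0.0717). Genomic DNA carried over into the Akita RNA stays open as a possible explanation. The 1394 olfactory and vomeronasal receptor genes, including the 5 that rose, had a median of 0.107. This lay at percentile 100 of 10000 lists matched on signal (matched median 0.0183). The 1814 probe sets of several genes had a median of 0.0592, also at percentile 100 (matched median 0.00833). These lists draw genes as if independent, so a small shift over many genes reaches that percentile, which does not measure the spread between arrays. By camera with an estimated correlation, both receptor families were at adjusted p = 0.907. The unlisted probe sets, whose loci are unknown, had a median of -0.015 (percentile 0). A difference in the copy number of these loci between the mice was not tested, nor was an effect of the diabetes itself.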

How the results depend on the processing

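No paired analysis was possible because the groups share fewer than 2 numbers. The alternatives given here were planned before the data were examined, except the families of the closing part without a filter. Camera called 12 families with the filter (8 higher, 4 lower) and 12 without it (6 higher, 6 lower). These were not the same families: Cyp, Krt, Mir, Kif and Cxcl lost their call and others gained one. The cause of each change was not tested unless its construction shows it. Among 2549 values of 185 named genes under the alternatives, 2376 kept their side of the threshold, 130 were no longer past it and 43 were newly past it. The sign turned in 31 values of 18 genes, 0 of them in a gene past the threshold. The 51 calls (33 higher, 18 lower) became 86 (68 higher) without a filter, 48 (20 higher, 28 lower; 34 shared with the 51) at the 50th percentile, 32 (21 and 11; 31 shared) with quantile normalization again, 30 (25 and 5; 29 shared) with arrays centred, 197 (60 and 137; 51 shared) with an intensity trend and robust prior, 28 (20 and 8; 28 shared) with array weights and 96 (49 and 47) at a threshold of 0.1. The unmoderated linear model called 0 (0 higher, 0 lower, 0 list members), with 1726 genes at an unadjusted p under 0.05. With an array left out the calls ranged from 9 to 40, from 9 to 37 higher and from 0 to 3 lower. The 2 list members past the threshold became 4 without a filter, 4 at the 50th percentile, 1 with quantile normalization, 1 with centring, 21 with the trend, 6 at 0.1 and 0 to 11 with an array left out. The 342 genes at an unadjusted p under 0.05 and a fold of at least 1.5 became 559 without a filter, 62 at a fold of 2 and 311 to 923 with an array left out, highest without Akita replicate 3 (517 without wild type replicate 5). The variance share of the groups ranged from 44.5% to 58.7% with an array left out, where chance gives 33.3% for 4 arrays and 25% for 5. The 10 called lists became 6 with quantile normalization, 16 with the trend, 0 with an estimated correlation, 0 by directional fry, 21 by mixed fry and 2 to 12 with an array left out.

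For single lists the adjusted p with an estimated correlation was 0.812 in each of the 10. By directional fry it was 0.268 for fatty acid use, 0.320 for cell division, 0.654 for extracellular matrix, 0.268 for immediate early genes, 0.268 for white adipocyte markers, 0.568 for epicardial markers, 0.268 for the respiratory chain, 0.593 for thymus, lung and liver markers, 0.450 for interferon response and 0.268 for oxidative stress. By mixed fry it was 0.192 for cell division, 0.272 for extracellular matrix, 0.272 for epicardial markers, 0.427 for thymus, lung and liver markers and 0.161 for interferon response. Without a filter it was 0.0766 for epicardial markers and 0.126 for thymus, lung and liver markers. At the 50th percentile it was 0.228 for the respiratory chain, 0.210 for interferon response and 0.209 for oxidative stress, and thymus, lung and liver markers were too few to test. With quantile normalization again it was 0.120 for epicardial markers, 0.161 for the respiratory chain, 0.179 for thymus, lung and liver markers, 0.0987 for interferon response and 0.230 for oxidative stress. With arrays centred it was 0.152 for the respiratory chain, 0.147 for thymus, lung and liver markers and 0.0707 for oxidative stress, and with the trend 0.0526 for interferon response. With an array left out the ranges were 1.30e-05 to 0.0108 for fatty acid use, 4.45e-08 to 0.186 for cell division, 2.19e-15 to 0.726 for extracellular matrix, 1.05e-05 to 0.248 for immediate early genes, 2.97e-04 to 0.112 for white adipocyte markers, 6.33e-06 to 0.613 for epicardial markers, 1.52e-04 to 0.772 for the respiratory chain, 0.00693 to 0.866 for thymus, lung and liver markers, 0.00323 to 0.436 for interferon response and 0.0414 to 0.204 for oxidative stress. By camera the matrix list alone turned direction, at 0.726 without Akita replicate 3; the median of thymus, lung and liver markers also turned, from 0.2 to -0.0333 without Akita replicate 1. An Akita array left alone was assumed to vary like the others. Array signal has no true background level here, so dim genes are open to it; the genes that rose were mostly dim.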

Other observations

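The tests of gene families, of atrial tissue, of the size of the falls and of a trend with mean signal were chosen after the data were seen. The test of gene length was made on the 18 genes already seen to fall, and only its shares of calls kept were fixed before its result. Genes grouped by the stem of their symbol gave 192 families, of which camera called 12, 8 higher and 4 lower in Akita; with an estimated correlation 0 were called, each of the 12 at adjusted p = 0.954. The mitochondrial ribosome lay lower: of 43 Mrpl genes 39 did (median -0.18, camera adjusted p = 4.49e-04; 0.954 with an estimated correlation), and of 27 Mrps genes 22 (median -0.15, adjusted p = 0.0199; 0.954 likewise). In both families 0 members passed the threshold, and the lowest p was that of Mrpl10 (log2 difference -0.63, SE 0.14, adjusted p = 0.165). Without Akita replicate 3 the Mrpl median was -0.17 and the Mrps median -0.10, and with the arrays centred they were -0.08 and -0.06, or -0.12 and -0.08 with quantile normalization again. Genes of the Mediator complex, which links transcription factors to RNA polymerase, lay lower in 25 of 30 cases (median -0.17, -0.11 without Akita replicate 1 and -0.07 with the arrays centred; adjusted p = 0.00734, and 0.954 with an estimated correlation). Lsm genes of RNA processing lay lower in 12 of 13 (median -0.19, -0.10 with the arrays centred; adjusted p = 0.0346, and 0.954 with an estimated correlation).

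Most families called higher lost their call without the filter. The filter is set on the mean of all arrays and so can admit genes through high Akita signals. Olfactory receptor genes (Olfr) lay higher in 98 of the 115 above it (median 0.217; adjusted p = 2.65e-15, and 0.954 with an estimated correlation), with a median of 0.107 without Akita replicate 1 and 0.407 without Akita replicate 3. Of the 115, 18 had a wild type mean under the filter. Over all 1105 Olfr genes on the array, 764 (69.1%) lay higher, with a median of 0.113 (adjusted p = 5.45e-08, and 0.907 with an estimated correlation). Vomeronasal receptor genes (Vmn) lay higher in 23 of 25 above the filter (median 0.385; adjusted p = 9.73e-13, and 0.954 with an estimated correlation), where 7 of the 25 had a wild type mean under it, and in 187 of all 289 (median 0.09; adjusted p = 7.72e-05, and 0.907 with an estimated correlation). Collagen genes lay higher in 38 of 41 cases (median 0.16, and 0.07 without Akita replicate 3; adjusted p = 1.87e-05, and 0.954 with an estimated correlation). The other families called higher were Cyp, Krt, Mir, Kif and Cxcl, with medians of 0.18, 0.163, 0.103, 0.13 and 0.208, each at 0.954 with an estimated correlation. Without Akita replicate 1 the Mir, Krt and Cxcl medians were -0.07, 0.0933 and 0.13, and without Akita replicate 3 the Kif median was 0.05. With the arrays centred the medians of all 8 families lay between 0.197 and 0.479, a rise that centring gives to every family. Without the filter none of Cyp, Krt, Mir, Kif and Cxcl was called, with medians of 0.0725, 0.137, -0.0183, 0.09 and 0.148, whereas the collagen genes and the 4 families called lower were. In Cyp, Krt, Mir, Kif and Cxcl, 3 of 35, 4 of 35, 6 of 163, 2 of 30 and 0 of 10 genes above the filter had a wild type mean under it. Few of their genes thus entered through high Akita signals, and a test without those genes was not run.

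The genes that fell were compact, with a median genomic span of 3.4 kb against 20.2 kb over all genes tested. With each array's trend with genomic length removed, 11 of the 18 kept their call, between the shares fixed beforehand for and against a trend with gene length. The median log2 difference of all 18 went from -0.962 (median SE 0.117) to -0.94 (median SE 0.111). The trend removed is an average over all genes tested and was small. Their median difference was -0.01 in the shortest, -0.0467 in the middle and -0.0183 in the longest length group. Among genes of above-median signal, for which no separate trend was fitted, it was -0.118 in the shortest and -0.0517 in the longest. Neither average is large enough to be the whole cause of the falls. An effect of length confined to some short genes, or to bright ones, would not be fully removed this way. The remaining fall thus does not decide on such an effect. Of the 7 calls that ended, 4 had a larger SE and 3 a smaller difference, with adjusted p up to 0.0751. The median log2 difference of these 7 went from -0.838 to -0.805. A trend with mean signal, removed alone, left 11 calls, and both trends together left 5. The medians over all 18 genes were then -0.901 (median SE 0.104) and -0.854 (0.107), so most of the fall remained in each case. For the 7, a part played by length cannot be told apart from small changes near the threshold; genomic span only stands in for transcript length, GC content was not tested, and a biological explanation through the diabetes is untested.

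Nppa and other atrial genes were highest in Akita replicate 3. More atrial tissue in that sample is a candidate explanation: 11 of 11 atrial genes other than Nppa lay higher there than in the mean of the other 4 arrays, by a median of 0.667, with Bmp10 at 5.79, Sln at 3.22 and Myl7 at 2.72. In Akita replicate 1, 9 of the 11 lay under the wild type mean, Myl7 by -1.45 and Sln by -1.23. Matrix, fibroblast and epicardial genes were higher in the same array, so their differences could reflect how the heart was sampled; a change in this one heart with diabetes is untested.

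Of the 10 splits of the 5 arrays into 3 and 2, only the real split gave as many as 51 genes past the threshold (1 of 10) and the highest other gave 0; 10 splits are too few for a share under 0.05.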
